A study of Mus musculus with 6 samples.

How the data were processed

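Liver mRNA from 6 mice was analysed, 3 control mice homozygous for floxed alleles of Nr1h4 (which encodes FXR) and Nr0b2 (which encodes SHP), and 3 mice lacking both genes in hepatocytes. Per the labels' protocols, livers were flash frozen, total RNA was isolated with a Qiagen kit, and libraries were made from 1 µg of RNA with Illumina's stranded mRNA kit. The groups and replicate numbers were taken from the sample titles, and each column of the deposited table was matched to a sample by the genotype word and number in its name.

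The submitters' processing notes name bcl2fastq 2.17.1.14, Trimmomatic, STAR 2.4.2a, Picard 1.119 and Cuffdiff 2.2.1 and the genome build GRCm38 (mm10), without giving the role or order of each. The gene annotation, the treatment of reads that map to several places, and the use of strand in counting are not given in the sources used here. The authors deposited FPKM (fragments per kilobase of transcript per 1e6 mapped fragments) for 48699 genes in each library. The authors also deposited a comparison of the groups with a group FPKM, a p-value and a q-value for each gene, in Cuffdiff's column layout per the file headers. All 6 columns of per-library values were used, and 0 others were present. FPKM divides by transcript length and by a library total, so a few very abundant transcripts, or a loss of fragments that depends on transcript length, shift the values of other genes. In 27 rows a spreadsheet had turned the gene symbol into a date, and these symbols were restored from the gene identifier. Positions, transcript lengths and GC content came from GENCODE M21 on GRCm38, in which 48343 of the identifiers were found. Where a symbol had several rows, the row with the highest mean FPKM was used.

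FPKM values are not counts, so no count model was used. Depth was read from the smallest steps of the FPKM values in genes over 1500 bases with 1 annotated transcript: the smallest values between 0.05 and 0.1 FPKM times kilobases clustered, in each library, around what 1 fragment is worth. That worth was between 0.0707 and 0.0758, from 273 to 299 genes per library, with a spread of 3.85% to 5.74%. It corresponds to between 13.2 and 14.1 fragments, times 1e6, in the library total that the authors' values were scaled to. Relative to control replicate 1, the depths lay between 1 and 1.07, so depth differed little between the groups. A gene of 1 kb at the filter of 0.5 FPKM then rests on few fragments, and low values carry large counting error.

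The comparison was made with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend in the moderated test and Benjamini-Hochberg adjustment at a threshold of 0.05. Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested, 11810 in all. A log2 fold change is the double knockout minus control difference on the log2(FPKM + 1) scale, which understates the change of low genes. Linear folds are ratios of the group mean FPKM. Values with an error are means ± SD over n = 3 mice. Groups of 3 against 3 cannot give an exact permutation p below 0.1, so single genes were tested only in the limma model. Each library was taken to be 1 mouse of its group. Limma's p-values for single genes rest on the spread between the 3 animals of a group, moderated towards the mean-variance trend of all tested genes.

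The 35 gene lists were fixed before the data were examined and held 637 members, of which 636 were found. They cover bile acids, N-glycosylation and the endoplasmic reticulum, lipid, glucose, amino acid and xenobiotic metabolism, the acute phase, complement, cell cycle, p53, fetal genes, sex-biased genes, the circadian clock, liver zones, and markers of hepatocytes and other cell types. The lists of lipid-linked oligosaccharide synthesis, the oligosaccharyltransferase complex and N-glycan trimming and branching were also joined as 1 combined list. Each list was tested with camera (preset correlation of 0.01 between genes, adjustment over all 36 tests), again with a correlation estimated per list, and with fry. Camera compares the genes of a list with the other genes. At the preset correlation it treats them as almost independent, so its p-values do not measure the spread between animals. Fry gives a directional p-value and a mixed one, which ignores direction. The title of the series that holds these libraries names N-glycosylation, so the direction of the lists on that theme is not independent evidence. Genes were named by a rule fixed before the data were examined: the deleted genes; the 10 highest and 10 lowest fold changes among genes past the threshold with a mean of at least 1 FPKM in a group and no overlap between the groups, leaving out predicted genes and pseudogenes; and, per list, up to 4 members past the threshold or else the most abundant members. Genes named outside that rule are marked as chosen after their values were seen.

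Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.25, no filter and a filter of 2 FPKM, median-ratio scaling, quantile normalization, no mean-variance trend, library weights, a replicate block, a minimum absolute log2 fold change of 1, the list tests above, and leaving out each library in turn. Chosen after seeing the data were the removal of a loess trend on transcript length and GC content from each library (span 0.5), leaving out both replicate 3 libraries, and a clock covariate (the first principal component of the circadian clock list).

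The scripts were tested on simulated libraries with the means and spread of this comparison, each with 200 genes changed. Of these, 0% were recovered at 1.5-fold and 0% at 2-fold, 82.5% at 4-fold (12 false calls) and 88% at 8-fold (7 false calls), among 11615 to 11642 genes tested. A list whose members were all raised alike, by more than its median in the real libraries, was called by camera (adjusted p = 1.63e-24). The simulated genes varied independently, so this does not test false calls among genes that move together. A simulated length trend with a rho of 0.524 was removed by the correction (rho of -0.00401 afterwards).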

Results

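Hepatic mRNA was measured in adult male C57BL/6 mice, 10 to 12 weeks old and fasted for 8 to 10 hours overnight. FXR is the nuclear receptor for bile acids, and SHP is an orphan nuclear receptor without a DNA-binding domain that represses transcription. The design compares 3 floxed control mice with 3 mice in which hepatocytes lack both receptors, and so asks which liver transcripts depend on the pair. Between 16087 and 16698 genes had an FPKM above 0 in a library, and the steps in the low values correspond to between 13.2 and 14.1 fragments, times 1e6, per library. The FPKM of all genes summed to 702759, 789099 and 841745 in the controls and to 688182, 610618 and 697877 in the knockouts. Albumin or, in double knockout replicate 2, Apoe was the most abundant transcript, with 2.93% to 5.53% of the sum.

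Both deleted genes were lower in each of the 3 knockout libraries. Nr0b2 (ENSMUSG00000037583.2, chromosome 4, 133553376 to 133556536, GRCm38) stood at 17.0 ± 2.10 FPKM in controls and 0.194 ± 0.111 FPKM in knockouts (SD, n = 3 each), a log2 fold change of -3.91 (SE 0.16, limma adjusted p = 0.000277). The other gene, Nr1h4 (ENSMUSG00000047638.15, chromosome 10, 89454234 to 89533585) measured 59.8, 71.8 and 68.0 FPKM in the controls and 21.1, 15.5 and 22.0 FPKM in the knockouts. Its mean fell 3.40-fold (log2 fold change -1.73, SE 0.17, limma adjusted p = 0.0172). The remaining Nr1h4 signal is a gene-level value, and exons outside the deleted part or cells other than hepatocytes would contribute to it. The Nr1h4 call was kept without control replicate 3 (limma adjusted p = 0.0156) and was lost when any 1 of the other 5 libraries was left out (0.0616 to 0.133), with its fold change between -1.58 and -1.82.

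In the knockouts, 20 genes were higher and 17 lower at the threshold, and 1765 genes had an unadjusted limma p under 0.05. A split of the libraries that mixes the groups, control replicates 1 and 2 with double knockout replicate 1, gave 1548 such genes. The control and knockout values did not overlap in all 37, which selection by a small p on the same values favours. They did not overlap in 22.9% of the tested genes, where chance gives 10%. On the log2(FPKM + 1) scale, Moxd1, a monooxygenase homologue, rose most, from 0.384, 0.290 and 6.54 FPKM to 121, 121 and 85.9 FPKM (log2 fold change 5.52, SE 0.63, limma adjusted p = 0.0278). Sult1e1, the oestrogen sulfotransferase, rose from 0.347 ± 0.262 to 43.3 ± 27.2 FPKM (4.84, SE 0.46, limma adjusted p = 0.0166) (SD, n = 3 each). Rian, a maternally expressed noncoding RNA of the imprinted Dlk1-Meg3 domain on chromosome 12, rose from 0.429 ± 0.336 to 14.3 ± 6.80 FPKM (log2 fold change 3.35). Mpeg1, a pore-forming protein of macrophages, rose from 5.12, 7.12 and 17.7 FPKM to 58.2, 73.5 and 57.3 FPKM. Ntrk2, which encodes the neurotrophin receptor TrkB, was near 0 in the controls (0.041, 0.075 and 0.057 FPKM) and between 3.26 and 6.17 FPKM in the knockouts. Abcg8, a subunit of the canalicular sterol transporter, rose 2.78-fold, from 25.6 ± 3.44 to 71.0 ± 7.42 FPKM (limma adjusted p = 0.0219, SD, n = 3 each). Rasgrp2, an exchange factor for Rap proteins, rose 2.94-fold and Rcan2, a regulator of calcineurin, 6.02-fold. Robo1, a guidance receptor, rose 6.85-fold, and Slc35f2, a solute carrier, from 0.0882, 0.0274 and 0.511 FPKM to 3.78, 3.11 and 2.47 FPKM. With the length and GC trend removed, Mpeg1, Robo1 and Rasgrp2 were not past the threshold (limma adjusted p = 0.0605, 0.0547 and 0.0539).

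Among the genes that fell, Mfsd2a, the transporter of lysophosphatidylcholine that carries docosahexaenoic acid, went from 63.3, 70.7 and 22.4 FPKM to 1.48, 0.270 and 2.55 FPKM (log2 fold change -4.41, SE 0.51, limma adjusted p = 0.0278). Ces1g, a carboxylesterase and lipid hydrolase on chromosome 8, went from 80.6 ± 20.5 to 7.26 ± 0.291 FPKM (-3.27, SE 0.20, limma adjusted p = 0.00226, SD, n = 3 each). Ces1b, of the same gene cluster but not adjacent to it, fell 5.18-fold. Of the genes of fatty acid metabolism, the ω-hydroxylases Cyp4a12b (13.1-fold) and Cyp4a14 (526 ± 55.1 to 114 ± 27.5 FPKM; SD, n = 3 each) fell. So did the acyl-CoA thioesterase Acot1 (5.72-fold) and malic enzyme, Me1 (3.69-fold). Olig1, a transcription factor of the oligodendrocyte lineage, was at 5.23, 4.82 and 2.03 FPKM in the controls and at most 0.135 FPKM in the knockouts. The Ces1, Cyp4a and Acot genes have close paralogs side by side on their chromosomes, and how reads shared between them were assigned is not given in the sources used here. The mitochondrial transcript mt-Nd3 was listed at 4.33, 7.19 and 5.43 FPKM against 1.08, 0 and 0.588 FPKM. The mitochondrial transcripts mt-Co2 and mt-Co3, chosen after their values were seen, were listed at only 0.854 to 5.02 FPKM, so this estimate is uncertain. With the length and GC trend removed, Cyp4a12b, Acot1, Me1 and mt-Nd3 were not past the threshold (limma adjusted p = 0.0567, 0.0571, 0.0567 and 0.113).

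**Figure D1:**
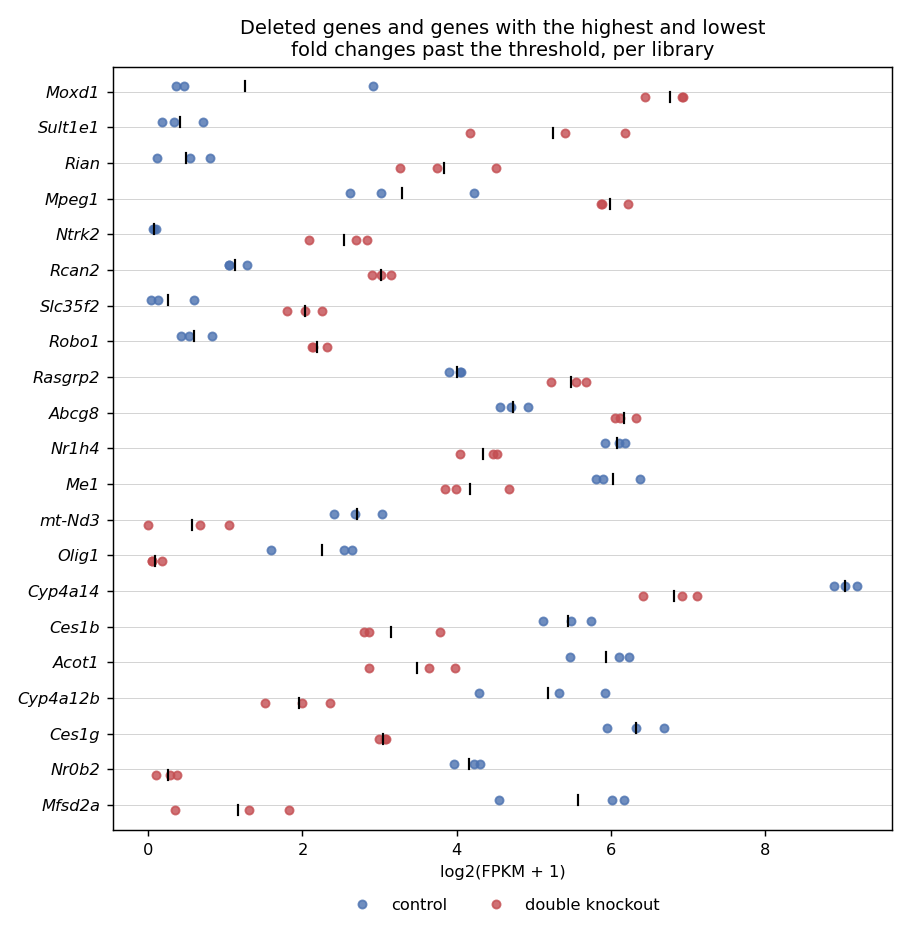
Expression, as log2(FPKM + 1), of the deleted genes and of the genes with the highest and lowest fold changes past the threshold, with 1 point per library (blue, control; red, double knockout), a black bar at each group mean, and genes ordered by log2 fold change. Apart from the deleted genes, the rule for naming required that the groups did not overlap, and they did not overlap in the deleted genes either. Moxd1 and Mpeg1 were higher in control replicate 3 (6.54 and 17.7 FPKM) than in the other controls.

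The count of genes depended on the library in the control group that stood apart. Without control replicate 3, 154 genes were higher and 88 lower, with all 37 of the original genes among them. Leaving out any 1 of the other 5 libraries left between 2 and 6 genes. Expression in control replicate 3 correlated with the other controls at 0.952 and 0.955 over log2 values, against 0.983 between those 2, across genes, which are not independent replicates. With double knockout replicates 1, 2 and 3 it correlated at 0.956, 0.954 and 0.966, so it was no closer to its own group. Control replicates 1 and 2 correlated with double knockout replicate 1 at 0.971 and 0.968, above their correlation with control replicate 3. Of 15 immediate-early genes looked at after their values were seen, 14 were highest in that library. Among them, Fos was at 53.7 FPKM against at most 2.60 FPKM, and Atf3 at 68.1 FPKM against at most 4.61 FPKM. The exception, Ier3, was highest in double knockout replicate 3 (3.37 FPKM against 1.33 FPKM), and Dusp1 was close in both (36.8 FPKM in control replicate 3 and 31.5 FPKM). The acute phase gene Saa1 was also highest in control replicate 3 (10483 FPKM).

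The authors' deposited table called 542 genes, 337 higher and 205 lower in the knockouts. Of 11689 genes with a test in both analyses, the authors' deposited table called 520, and 35 of the 37 limma calls were among them, all in the same direction. Both analyses use the same 6 libraries, so the sharing is not independent evidence. The other 2 were Dnajc1 and Sult5a1, chosen after their values were seen. Of the 520, 444 had an unadjusted limma p under 0.05, and the groups did not overlap in 79.0%, against 23.1% of the genes in both analyses and 10% by chance. In the authors' deposited table, genes called lower included 10 of these 15 immediate-early genes, and all 10 were highest in control replicate 3. The direction of 14 genes in the authors' deposited table, all called lower there, turned when control replicate 3 was left out of the means.

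Of the N-glycosylation lists, the list of genes that trim and branch the glycan after its transfer lay higher in the knockouts as a whole. The lists that build and transfer it were not called. In the trimming and branching list, 15 of 19 measured members had a positive fold change, with a median log2 fold change of 0.20 (camera adjusted p = 0.00186; adjusted p = 0.516 with an estimated correlation). None of its members passed limma's threshold over all genes; 3 were higher when adjusted over the list alone, St6gal1, Fut8 and Mgat5. St6gal1, which adds α2,6-linked sialic acid, measured 17.8, 18.3 and 21.3 FPKM in controls and 41.5, 35.6 and 45.8 FPKM in knockouts (log2 fold change 1.06, limma adjusted p = 0.0539 over all genes). Fut8, the core fucosyltransferase, measured 1.30 ± 0.225 and 3.39 ± 0.536 FPKM, and Mgat5, which starts the β1,6 branch, 0.907 ± 0.194 and 2.15 ± 0.253 FPKM (SD, n = 3 each; limma adjusted p = 0.0868 and 0.141); these 3 genes were chosen after their values were seen. The authors' deposited table gave q-values of 0.0319 for St6gal1, 0.00121 for Fut8 and 0.00121 for Mgat5. The most abundant members, Prkcsh and Man1a, had fold changes of -0.15 and -0.04. Both act in trimming, as do Mogs and Ganab, which did not rise either, so the rise was not shared by all trimming genes. The title of the series that holds these libraries names N-glycosylation, so the direction of the list is not independent evidence.

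In lipid-linked oligosaccharide synthesis, 10 of 28 members had a positive and 18 a negative fold change (median -0.08, camera adjusted p = 0.268), none past limma's threshold. Dpm3, a subunit of dolichol-phosphate mannose synthase, was at 95.0 ± 19.2 and 66.0 ± 4.10 FPKM, and Dpm1 at 77.8 ± 10.7 and 63.5 ± 7.39 FPKM (SD, n = 3 each). The authors' deposited table called 1 of the list, Alg10b, higher (q = 0.00121), chosen here after its values were seen. The oligosaccharyltransferase complex had 4 positive and 8 negative fold changes (median -0.26, camera adjusted p = 0.401), with Dad1 at 95.3 ± 13.0 and 79.3 ± 15.0 FPKM and Rpn2 at 78.3 ± 5.59 and 83.1 ± 13.3 FPKM (SD, n = 3 each). The median of the complex was -0.00 without control replicate 3 and -0.13 without double knockout replicate 2. Joined, the 59 N-glycosylation genes had 29 positive and 30 negative fold changes, a median of -0.01 and a mean of 0.03 (camera adjusted p = 0.756), and 0 past limma's threshold. Fry's mixed test, which ignores direction, called the joined list (fry mixed adjusted p = 0.00887). It also called the trimming and branching list within it (0.00320), but not the synthesis (0.383) or oligosaccharyltransferase (0.537) list. Nucleotide sugar supply had 8 of 21 positive (median -0.14, camera adjusted p = 0.260), with Gne, the entry enzyme of sialic acid synthesis, at 84.9 ± 10.2 and 54.5 ± 13.0 FPKM (SD, n = 3 each, not past the threshold).

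**Figure D2:**
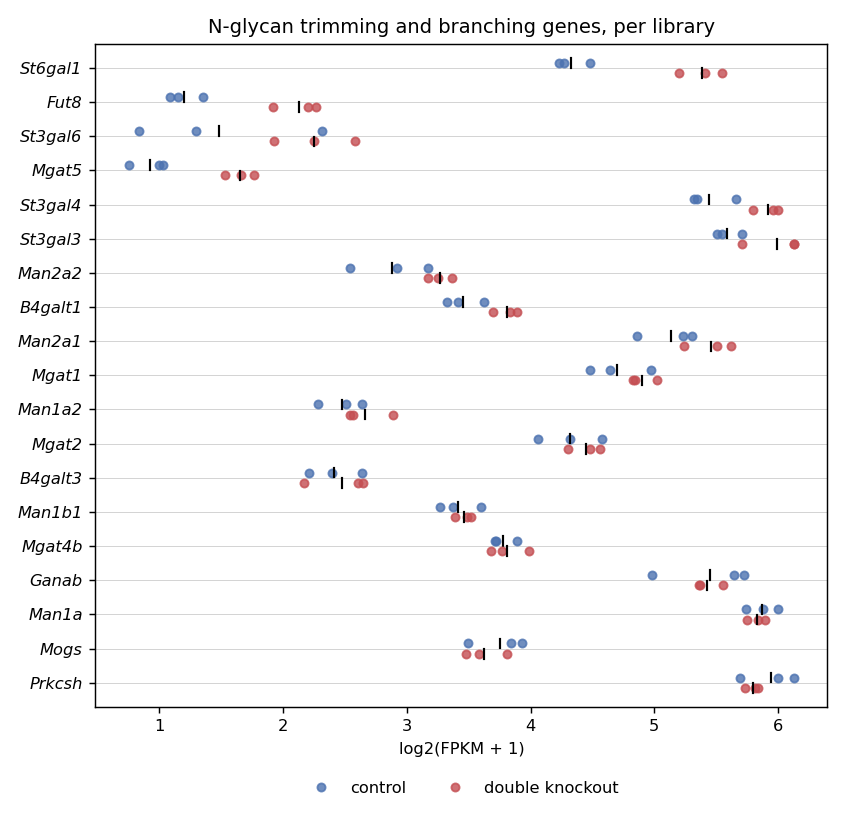
Expression, as log2(FPKM + 1), of the 19 measured genes of N-glycan trimming and branching, with 1 point per library (blue, control; red, double knockout), a black bar at each group mean, and genes ordered by log2 fold change. The 3 knockout values lay above the 3 control values in St6gal1, Fut8 and Mgat5, while Prkcsh, Mogs, Man1a and Ganab had group means at or below the control mean.

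Of the lists of the endoplasmic reticulum, the chaperone and the translocon list lay lower. Of the unfolded protein response and chaperone genes, 21 of 25 had a negative fold change (median -0.36, camera adjusted p = 0.0133; adjusted p = 0.864 with an estimated correlation), with 0 past limma's threshold. The chaperones Hspa5 (289 ± 113 and 208 ± 56.2 FPKM) and P4hb (570 ± 186 and 409 ± 44.7 FPKM) were its most abundant members (SD, n = 3 each). Adjusted over the list alone, Ddit3 was lower and Asns higher, both chosen after their values were seen. Asns, asparagine synthetase, measured 4.68 ± 5.50 and 29.0 ± 0.822 FPKM (SD, n = 3 each), and was past the threshold over all genes without control replicate 3 (log2 fold change 3.61, limma adjusted p = 0.00153). The translocon and signal peptidase list had 18 of 22 negative (median -0.29, camera adjusted p = 0.0169; adjusted p = 0.864 with an estimated correlation), among them Ssr4 (161 ± 63.8 and 99.6 ± 17.6 FPKM) and Sec61b (171 ± 46.6 and 132 ± 30.0 FPKM) (SD, n = 3 each). The calnexin cycle and degradation list was not called (median -0.04, camera adjusted p = 0.482), with Calr at 344 ± 64.3 and 257 ± 44.7 FPKM and Herpud1 at 335 ± 135 and 211 ± 80.9 FPKM (SD, n = 3 each). The mean log2 deviations of the chaperone and translocon lists were -0.21 and -0.17 in control replicate 1, and -0.12 and -0.18 in double knockout replicate 1, so the groups were not apart in each library. Without control replicate 3, the chaperone and translocon lists were not called (camera adjusted p = 0.0583 and 0.234), and without double knockout replicate 2 the translocon list was not (0.102). Quantile normalization (camera adjusted p = 0.128 and 0.290) and a filter of 2 FPKM (0.0612 and 0.0609) ended both calls, and library weights the translocon call (0.104).

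Fatty acid oxidation and PPARA target genes were lower. Of 24 measured, 17 had a negative fold change (median -0.38, camera adjusted p = 0.00186; adjusted p = 0.747 with an estimated correlation), and 3 fell past limma's threshold. These were Acaa1b, a peroxisomal thiolase, from 689 ± 83.6 to 200 ± 10.1 FPKM (log2 fold change -1.77, limma adjusted p = 0.0155), Cyp4a14 (-2.22) and Acot1 (-2.45) (SD, n = 3 each). With the length and GC trend removed, Acot1 was not past the threshold. Adjusted over the list alone, 9 were lower and 1 higher; the higher one was Vnn1, a pantetheinase (28.5 ± 2.49 and 57.2 ± 8.75 FPKM, SD, n = 3 each), chosen after its values were seen. The fatty acid and triglyceride synthesis list was not called (13 of 19 positive, median 0.34, camera adjusted p = 0.123): Me1 fell, while Scd1, at 1382 ± 712 and 1472 ± 1531 FPKM (SD, n = 3 each), differed by less than its spread. Fads2 was at 180 ± 109 and 365 ± 152 FPKM (SD, n = 3 each, limma adjusted p = 0.314). The authors' deposited table called 5 genes of that list higher, Fads2 among them (q = 0.0125), and 1 lower. That list was called higher under quantile normalization (camera adjusted p = 0.0290) and without double knockout replicate 2 (0.00946), and its median was 0.07 without control replicate 3. The cholesterol list was not called either (median -0.17, camera adjusted p = 0.756), and its level varied within both groups. Its mean log2 deviation from the control mean was highest in control replicate 3, 0.82 in double knockout replicate 3, and between -0.69 and -0.44 in the other 4 libraries. Without control replicate 3 the cholesterol list lay higher (median 0.45, camera adjusted p = 0.0384), and without double knockout replicate 3 it lay lower (-0.59, camera adjusted p = 0.0122). The lipoprotein list had 14 of 19 negative (median -0.32, camera adjusted p = 0.253), with Apoe at 23528 ± 3053 and 18879 ± 2292 FPKM (SD, n = 3 each). Quantile normalization ended the call of the fatty acid oxidation list (camera adjusted p = 0.102).

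Bile acid synthesis, a pathway in which FXR and SHP are known to repress some genes, was not called as a list (7 of 15 positive, median -0.06, mean 0.02, camera adjusted p = 0.870), with 0 members past limma's threshold. A list test of a shared direction does not decide whether single members were derepressed. Cyp7a1, its rate-limiting enzyme, chosen after its values were seen, measured 28.6, 36.2 and 181 FPKM in the controls and 102, 118 and 126 FPKM in the knockouts (limma adjusted p = 0.484). Without control replicate 3, Cyp7a1 was past the threshold (log2 fold change 1.80, limma adjusted p = 0.00932), the only member of the list that was. Scp2 was at 2107 ± 122 and 1647 ± 162 FPKM and Akr1c6 at 932 ± 423 and 930 ± 85.7 FPKM (SD, n = 3 each). In bile acid and phospholipid transport, 8 of 12 members were positive (median 0.10, camera adjusted p = 0.365); Abcg8 rose, and adjusted over the list alone Abcg5 was also higher and Slco1a1 lower, both chosen after their values were seen. Slco1b2 and Slc10a1, uptake carriers for bile acids, were at 456 ± 192 and 484 ± 59.0 FPKM and at 376 ± 40.1 and 372 ± 102 FPKM (SD, n = 3 each).

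Urea cycle and amino acid breakdown genes were lower, with 14 of 17 negative (median -0.45, camera adjusted p = 0.00186; adjusted p = 0.864 with an estimated correlation). None passed limma's threshold over all genes, and 6 were lower when adjusted over the list alone, Otc, Asl, Arg1, Gls2, Tdo2 and Hal, chosen after their values were seen. The mean log2 deviation of the list from the control mean was -0.46 and -0.78 in double knockout replicates 1 and 2, but -0.13 in double knockout replicate 3, which lay above control replicate 3 (-0.18). Ass1, argininosuccinate synthase, was at 2690 ± 380 and 1664 ± 439 FPKM and Hpd at 1695 ± 206 and 1477 ± 199 FPKM (SD, n = 3 each). The list of periportal hepatocyte markers, which shares Ass1, Arg1, Hal and Gls2 among others with it, was lower (9 of 12 negative, median -0.81, camera adjusted p = 0.0295; adjusted p = 0.864 with an estimated correlation), while the pericentral list was not called (median 0.06, camera adjusted p = 0.474). The periportal deviation was likewise -0.60 and -0.66 in double knockout replicates 1 and 2 and -0.05 in double knockout replicate 3, against -0.20 in control replicate 3. Of the pericentral markers, Cyp2e1 was at 6126 ± 629 and 5586 ± 954 FPKM and Oat at 653 ± 73.4 and 1017 ± 114 FPKM (SD, n = 3 each). The periportal call was lost when control replicate 1, control replicate 2, double knockout replicate 1 or double knockout replicate 2 was left out (camera adjusted p = 0.121, 0.0580, 0.124 and 0.0741). Quantile normalization ended both the urea cycle and the periportal call (0.133 and 0.158), and a filter of 2 FPKM (0.0719) and the clock covariate (0.0643) the periportal call.

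Genes that are higher in female than in male mouse liver lay higher in the knockout males. Of 9 measured, 7 had a positive fold change (median 0.86, camera adjusted p = 0.0115; adjusted p = 0.516 with an estimated correlation). Ntrk2 rose, and Cyp2b9 was higher when adjusted over the list alone (at most 0.195 FPKM in controls and 13.8, 4.60 and 1.58 FPKM in knockouts, chosen after its values were seen). Cyp17a1 was at 18.4 ± 11.4 and 56.0 ± 39.1 FPKM and Acot3 at 11.3 ± 13.9 and 3.71 ± 3.24 FPKM (SD, n = 3 each). The 9 measured are part of a list of 19, and the other 10 lay under the filter of 0.5 FPKM. That filter uses the mean of both groups, so genes near 0 in controls, such as Ntrk2 and Cyp2b9, enter only through their knockout values, which favours a positive median. With no filter the median of the list was 0.06 (camera adjusted p = 0.0417). The male-biased list was not called (7 of 15 positive, median -0.16, camera adjusted p = 0.401), and Cyp4a12b fell. The abundant Serpina1e (8338 ± 1044 and 9601 ± 1843 FPKM) and Mup7 (7007 ± 2173 and 6206 ± 1467 FPKM) differed by less than the SD of the knockouts (SD, n = 3 each). The male-biased median ran from -0.40 without control replicate 2 to 0.13 without double knockout replicate 3, so its direction depended on the library left out.

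Markers of Kupffer cells and of stellate cells lay higher. All 14 measured Kupffer cell markers had a positive fold change (median 0.48, camera adjusted p = 0.0133; adjusted p = 0.864 with an estimated correlation), 0 past limma's threshold. Cd5l was at 27.0 ± 21.8 and 52.1 ± 30.3 FPKM and Clec4f at 33.7 ± 13.3 and 44.5 ± 24.6 FPKM (SD, n = 3 each). The mean log2 deviation of the list from the control mean was 1.40 in double knockout replicate 2 and 0.70 in control replicate 3, against 0.19 and 0.09 in the other knockouts. Without double knockout replicate 2 the list was not called (camera adjusted p = 0.426), nor without control replicate 1 (0.0599) or control replicate 2 (0.0807). Of the stellate and fibroblast markers, 12 of 15 were positive (median 0.38, camera adjusted p = 0.0192; adjusted p = 0.864 with an estimated correlation), with Dcn at 61.4 ± 20.3 and 63.4 ± 30.2 FPKM and Col3a1 at 5.64 ± 3.81 and 9.28 ± 6.15 FPKM (SD, n = 3 each). The mean log2 deviation of the stellate list was -0.17 in double knockout replicate 1, under the 0.22 and 0.18 of control replicates 2 and 3. That call ended without control replicate 1 (camera adjusted p = 0.326), double knockout replicate 2 (0.208) or double knockout replicate 3 (0.0879). Quantile normalization (0.0848), the length correction (0.0517), a filter of 2 FPKM (0.0783), library weights (0.215) and the clock covariate (0.0556) ended it too. The lists of cholangiocytes (median 0.28, camera adjusted p = 0.0836), sinusoidal endothelial cells (-0.10, 0.756), lymphocytes and neutrophils (0.10, 0.859), blood cell RNA (-0.62, 0.859) and hepatocytes (-0.14, 0.157) were not called. Of the hepatocyte markers, 14 of 16 had a negative fold change, and their median was -0.37 without control replicate 3 (camera adjusted p = 0.0514) and -0.33 without both replicate 3 libraries (0.0324). With the length and GC trend removed, the cholangiocyte list was called higher (camera adjusted p = 0.0184), and Spp1 was past the threshold (limma adjusted p = 0.0425). Without double knockout replicate 2, the sinusoidal endothelial list (median -0.32, camera adjusted p = 0.0106) and the blood cell list (-1.53, 0.0265) were called lower. Albumin was at 40888 ± 3459 and 24950 ± 8925 FPKM, and the cholangiocyte marker Spp1 at 36.0 ± 5.95 and 58.5 ± 2.96 FPKM (SD, n = 3 each; limma adjusted p = 0.381 and 0.146).

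The acute phase list lay higher (14 of 21 positive, median 0.37, camera adjusted p = 0.0461; adjusted p = 0.864 with an estimated correlation), with 0 members past limma's threshold, and its level varied within both groups. Saa1, the serum amyloid gene, measured 125, 130 and 10483 FPKM in the controls and 621, 5462 and 5050 FPKM in the knockouts. Hpx, haemopexin, was at 4046 ± 2772 and 3557 ± 1141 FPKM (SD, n = 3 each). Leaving out control replicate 1 (camera adjusted p = 0.426), control replicate 2 (0.124), double knockout replicate 2 (0.0814) or double knockout replicate 3 (0.0705) ended the call, as did no filter (0.0773) and the clock covariate (0.0955), and without control replicate 3 it was at 0.000220. The clock list was not called (median 0.23, camera adjusted p = 0.393), and its genes split the libraries otherwise than by genotype. Dbp measured 63.0 FPKM in control replicate 3 and 71.9 FPKM in double knockout replicate 3, and between 2.87 and 16.8 FPKM in the other 4. Of the lists left, none was called by camera. These were xenobiotic metabolism (median -0.16, camera adjusted p = 0.354), NRF2 targets (0.05, 0.675), one-carbon metabolism (-0.05 with a mean of 0.02, 0.772) and glucose production and glycolysis (0.10, 0.509). The others were complement and coagulation (-0.02, 0.859), cell cycle (-0.07, 0.723), p53 targets (-0.03 with a mean of 0.16, 0.491) and fetal liver genes (0.54, 0.157). The fetal liver list was called higher without control replicate 3 (camera adjusted p = 0.0326) and with the length and GC trend removed (0.0363). Of the 10 lists that camera called, fry's directional test called N-glycan trimming and branching (fry adjusted p = 0.0408), fatty acid oxidation (0.0483) and female-biased genes (0.0483). It did not call the chaperone (0.252), urea cycle (0.305), periportal (0.390) and translocon (0.451) lists, nor the Kupffer cell, stellate cell and acute phase lists (0.725 each). Fry's mixed test, which ignores direction, also called the urea cycle (fry mixed adjusted p = 0.0226) and periportal (0.0278) lists. It called lists that camera did not as well, among them bile acid and phospholipid transport (0.000748) and complement and coagulation (0.00320). The cholangiocyte (0.00188), male-biased (0.00320), fatty acid and triglyceride synthesis (0.00887) and combined N-glycosylation (0.00887) lists were also among them.

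**Figure D3:**
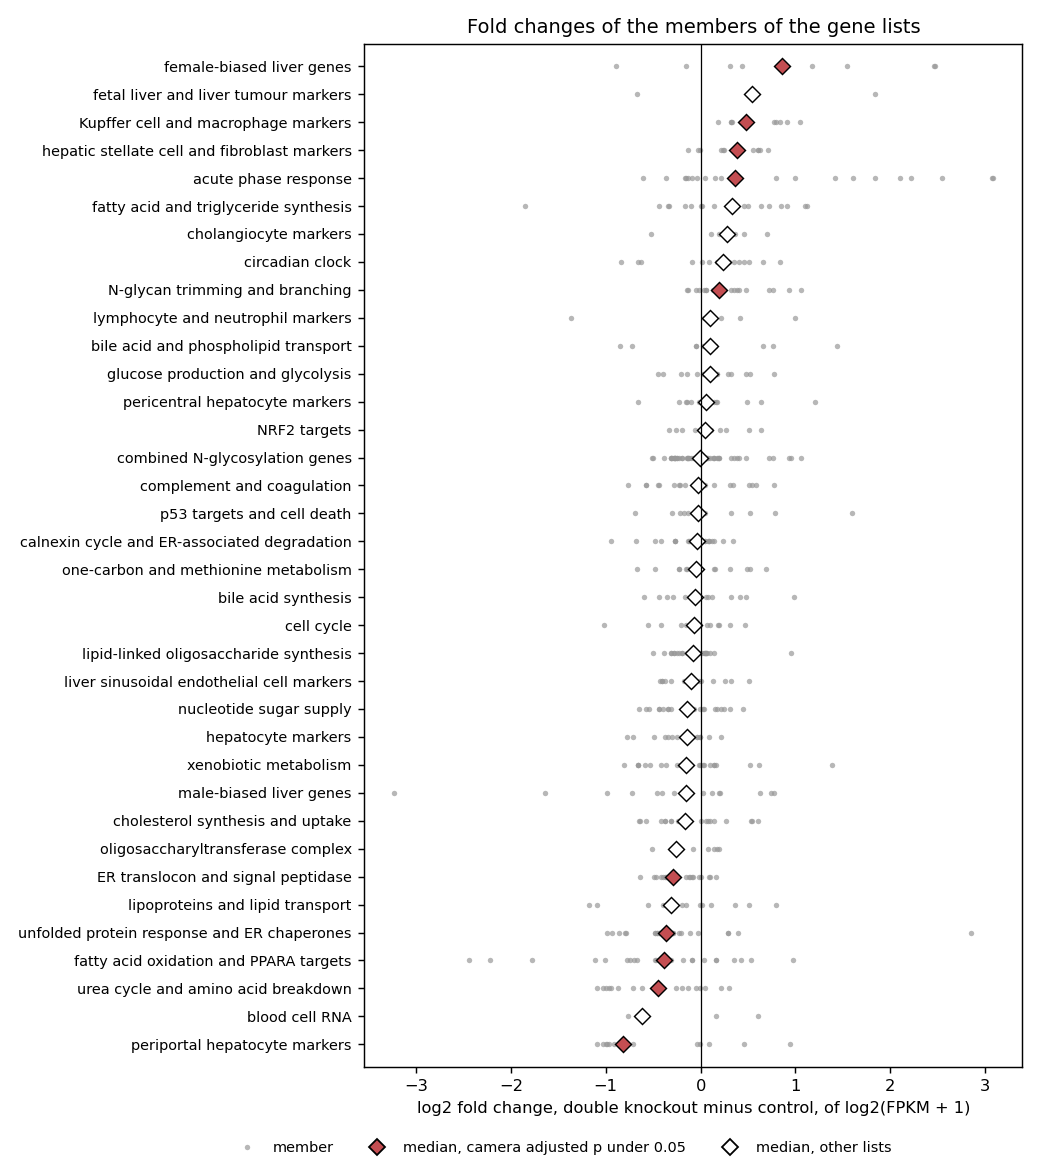
Log2 fold change (double knockout minus control, of log2(FPKM + 1)) of each measured list member (grey points) and the list median (diamonds, red where camera's adjusted p was under 0.05), for the 35 lists and the combined N-glycosylation list, ordered by median. Of the 10 lists in red, 5 have a negative median, from -0.81 for periportal markers to -0.29 for the translocon, and 5 a positive one, from 0.20 for N-glycan trimming and branching to 0.86 for female-biased genes.

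Fold changes followed transcript length. Across genes, which are not independent replicates, Spearman's rho between the log2 fold change and the longest annotated transcript was 0.40 over 11791 genes, and 0.25 without control replicate 3. The median fold change was -0.29 in 968 genes under 1 kb and 0.23 in 562 genes of 8 kb and over. Per library, rho was 0.0603, -0.194 and -0.381 in the controls and 0.278, 0.365 and 0.160 in the knockouts (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). The genes that the authors' deposited table calls higher had a median transcript of 4777 bases, and those it calls lower 2125 bases, among genes tested in both analyses. All genes tested here had a median of 3142 bases. Short gene families lay lower: 77 of 77 cytosolic ribosomal protein genes (median -0.36), 74 of 77 mitochondrial ribosomal protein genes (-0.39), 71 of 74 respiratory chain and ATP synthase genes (-0.49) and 32 of 37 proteasome genes (-0.41) had a negative fold change. These families were chosen after their values were seen, and their medians stayed negative in each setting named next, with smaller values. In the order given, the medians were -0.12, -0.26, -0.27 and -0.22 under quantile normalization, with 66 of 77 cytosolic ribosomal protein genes negative. They were -0.15, -0.24, -0.28 and -0.20 with the length and GC trend removed, and -0.12, -0.28, -0.35 and -0.25 without control replicate 3. The median transcript was 3755 bases in the N-glycan trimming and branching list, 2712 in the oligosaccharyltransferase complex and 2975 in the translocon list. With the length and GC trend removed, the medians of these 3 lists were 0.19, -0.08 and -0.12 (camera adjusted p = 0.00625, 0.519 and 0.0163), and 32 genes were past the threshold, 24 of them shared with the 37.

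**Figure D4:**
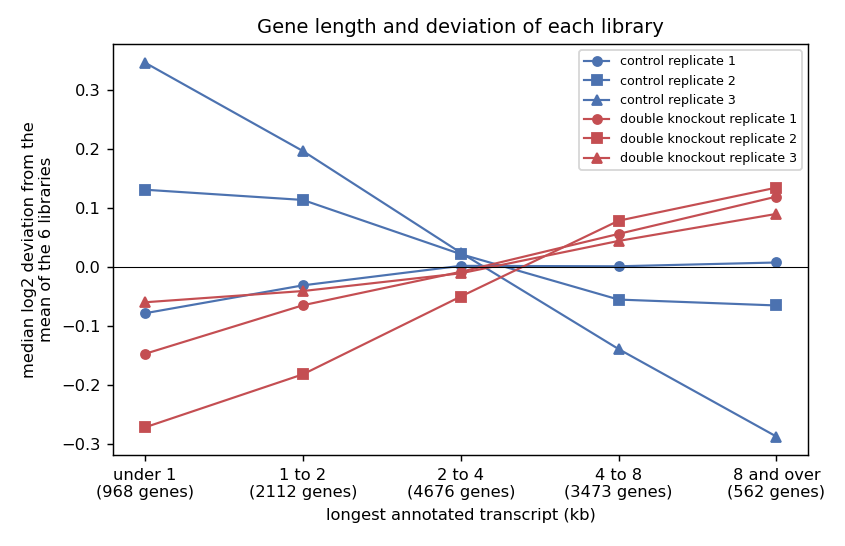
Median log2 deviation of each library from the mean of the 6 libraries, for genes in 5 classes of longest annotated transcript (kb), with 1 line per library (blue, control; red, double knockout; symbols, replicate number). In genes under 1 kb the medians ran from -0.27 in double knockout replicate 2 to 0.35 in control replicate 3, and in genes of 8 kb and over the order was turned, from -0.29 in control replicate 3 to 0.13 in double knockout replicate 2.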

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

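Removing the length and GC trend, leaving out both replicate 3 libraries and the clock covariate were chosen after the data were seen. A direction was counted as reversed only where the main value or the alternative was past the threshold. No gene past the threshold changed direction, and Nr0b2 stayed past it throughout. The cause was not tested where none is given.

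Against 20 genes higher and 17 lower, a pseudocount of 0.1 gave 13 higher. With no filter, 19705 genes were tested, 0 were higher and 2 lower, and Nr1h4 (-1.73) had an adjusted p of 0.0654. Library weights gave 326 higher and 237 lower, leaving out both replicate 3 libraries 84 and 74, and the clock covariate 49 and 54. Of the combined N-glycosylation genes, 0 passed at first, against 1 with a mean of at least 2 FPKM, 1 under quantile normalization, 6 under library weights, 1 without both replicate 3 libraries and 1 with the clock covariate. Leaving out each library in turn gave 0 to 154 higher, 2 to 88 lower, 0 to 2 combined N-glycosylation genes, and -1.82 to -1.58 for Nr1h4. The median of the cholesterol list ran from -0.59 to 0.45 in these fits, and was reversed without control replicate 3 (0.45, adjusted p = 0.0384). Of the 10 lists called, 9 stayed called with no filter, 6 with a mean of at least 2 FPKM, 4 under quantile normalization, 8 under library weights, 9 with the length trend removed, 7 without both replicate 3 libraries and 7 with the clock covariate. With fry's directional test 3 stayed called, and 0 with camera at an estimated correlation.

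The replicate block gave 27 higher and 23 lower, with 30 of the 37 genes and 9 of the 10 lists still called. Deviations of same-numbered libraries correlated at 0.220, -0.0754 and 0.301. Not every pair was above 0.1, and not every library correlated best with its own number, so the numbers were not used as pairs, though 3 correlations cannot rule out a link between some of them. In simulated libraries with 3 animals per group and 200 genes changed, 2-fold changes were not recovered. That result holds for this simulation and is not a general limit of 3 animals. In the real libraries Dnajc1, chosen after its values were seen, was called at 1.95-fold (limma adjusted p = 0.0490). Changes of that size can still be missed, so an absent call does not show that a gene was unchanged.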

Other observations

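The genes of this paragraph were chosen after their values were seen. Meg3, which lies beside Rian, measured 1.54, 1.79 and 0.153 FPKM in controls and 34.8, 11.6 and 6.13 FPKM in knockouts (limma adjusted p = 0.126). Within the carboxylesterase 1 cluster, Ces1b and Ces1g fell. Ces1c, Ces1d and Ces1e had fold changes of -0.84, -1.10 and -1.04 that were not past the threshold, and Ces1f one of -0.00. Of 9 targets of amino acid stress, 7 passed the filter and none was past the threshold. Positive were Asns (2.85, limma adjusted p = 0.126, and 0.00153 without control replicate 3) and Sesn2 (0.52). Negative were Fgf21 (-1.01), Ddit3 (-0.94), Chac1 (-0.48), Trib3 (-0.23) and Atf5 (-0.20). The groups did not overlap in Asns, Sesn2, Fgf21, Ddit3 and Chac1, nor in 22.9% of all tested genes. These 5 genes differ in direction and were chosen after their values were seen, so their number is not set against chance. Among the genes of this paragraph not past limma's threshold, the authors' deposited table called Meg3 and Asns higher (q = 0.00121 each). It called Ces1d (q = 0.00121), Ces1e (0.00226) and Fgf21 (0.0226) lower. Sesn2, Ddit3, Chac1, Trib3, Atf5, Ces1c and Ces1f were not called there. Psat1 and Phgdh lay under the filter.

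Chosen after the result was seen were the tests of the splits, of a wrong label, of the clock, of a length bias that follows the groups, and of the length trend in the N-glycan list. Of the 10 splits of the libraries into 3 and 3, only 1, the real one, gave as many as 37 genes, and the highest other gave 1. By an unadjusted limma p under 0.05 the real split stood out less, with 1765 genes. Setting control replicates 1 and 2 and double knockout replicate 1 against the other libraries gave 1548. The 10 splits are too few for a share under 0.05.

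More genes were past the threshold without control replicate 3 (242 against 37). A control 3 library that was a mislabelled knockout is argued against by its Nr0b2 of 18.7 FPKM. A length and GC trend in that library as the whole cause is argued against by 240 genes with the trend removed, against 32 with all libraries. A clock covariate gave 103 genes, which lies between both counts, so another clock phase cannot be told apart from other differences of that animal. Stress or handling of that animal stays open as untested.

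Short transcripts lay lower and long ones higher in the knockouts. The 265 genes of the 4 short families do not carry this, as rho was 0.384 without them. The rho with length spanned 0.441 among controls and 0.205 among knockouts, against a gap of 0.439 between the group means. A length bias of the libraries or RNA that happens to follow the groups therefore cannot be told apart from an effect of genotype, because it varies within the controls as much as between the groups.

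The N-glycan trimming and branching list lay higher. The length trend as the whole cause is argued against by an adjusted p of 0.00625 with it removed (median 0.19, against 0.20). The acute phase state is argued against by an adjusted p of 0.00273 with that covariate (median 0.29), and Kupffer cell RNA by an adjusted p of 0.000781 (median 0.28). These p-values use camera's preset correlation, and an estimated one gave 0.516, so the call itself stays open. A dependence of these genes on FXR and SHP remains a hypothesis, found and tested in the same libraries. Over all tested genes, the Kupffer cell covariate left 3 past limma's threshold and the acute phase covariate 55, against 37 without a covariate.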
